A study of Danio rerio with 12 samples.

How the data were processed

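The data are ATAC-seq profiles of whole zebrafish embryos at 32 hours post fertilization, from supt16h mutants and wildtype siblings. Per the labels' protocols, embryos were deyolked and dissociated, 50000 cells were lysed, nuclei were treated with Tn5 transposase, and amplified, size-selected libraries were sequenced on an Illumina HiSeq4000. The labels list 12 libraries, 6 per group, and the series text describes 3 biological replicates in 2 technical replicates each. CASAVA 1.8, FastQC 0.11.2 and HOMER 4.9 and the genome build GRCz10 (danRer10) are named in the submitters' processing notes. The aligner, any read filter, any removal of duplicate or mitochondrial reads and any shift of reads for the Tn5 footprint are not given in the sources used here, so their effect on the values cannot be judged.

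The deposited table holds 16555 entries, each a window of 4000 bp centred on an annotated start site, with 12 library columns named by group, biological number and technical number, per the file headers. The library columns hold normalized values on a log2 scale, deposited by the authors without naming the transformation. Windows without tags stand at 0 in all libraries, near-empty windows sit at a common floor, and differences between groups are smaller than the log2 fold changes in the same table, the behaviour of a log transformation that shrinks low values. Differences and folds computed from these columns are therefore on that shrunken log2 scale and understate the change, most of all at weak windows. The authors' deposited table also gives a log2 fold change, a p-value and an adjusted p-value per window for mutant versus wildtype, and the file does not name the test behind these p-values. The sign of that fold change is opposite to mutant minus wildtype in the library columns. HOMER's comparisons of replicates are known to put the reference group first in such headings, which would make a negative value mean higher in the mutants, as in the library columns, but the file does not state this. No counts are given, so the read depth is unknown, and no interval or floor that needs depth is given.

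Repeated entries for the same window were collapsed, leaving 15674 windows, of which 16 had no tags. Values of collapsed entries differed by at most 0.219. Gene names were those of the table, and 548 of 567 entries without a name were named through their RefSeq accession in the reference gene table. In 13 windows a spreadsheet date stands in place of the gene symbol, and these were left as they are. Accessions that map to several places account for 171 windows, and 143 windows lie on unplaced contigs. Windows were tested where the mean log2 value was at least 4, which left 15431.

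The design fixed before the data were examined assumed counts. It asked for a count model, and for technical pairs to be found by a chi-square test, with 6 libraries against 6 as the main fit where that test did not show pairs. Because the table holds log2 values and not counts, limma was used, as the same design foresaw for normalized values, and the pair test could not be run. The columns name the technical pairs, so the main fit averages each pair and compares 3 biological replicates with 3. This departs from the fixed design, was chosen after the table was seen, and the fit of 6 against 6 is given beside the number of calls. By their values, wildtype technical pairs were no closer than wildtype libraries of different biological replicates (SD of the difference between libraries 0.184 to 0.204 against 0.166 to 0.261), while mutant pairs were closer (0.111 to 0.187 against 0.189 to 0.237). Over windows the median SD was 0.111 between technical repeats and 0.0926 between biological means of a group. The level filter was also set after the table was seen, in place of a filter on counts.

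Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust options), with Benjamini-Hochberg adjustment over all tested windows and a threshold of 0.05. Windows of neighbouring start sites can overlap and are not independent. Gene lists (17, fixed before the data were examined) were tested on the window with the highest mean signal of each gene, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry, all from limma, adjusted over the lists. Called members were counted over all windows and adjusted over the list alone. Each list's median was set beside the median of 10000 random gene lists matched on mean signal. Of the genes in the lists, mef2cb is in 2 lists, and lists for tissues overlap in what a whole embryo expresses. The 16 lists reported cover FACT and histone chaperones, Polycomb, Notch, blood stem cells, endothelium, primitive erythrocytes, myeloid cells, skeletal muscle, neural tissue, neural crest and pigment cells, heart, endoderm, epidermis, cell cycle and replication, ribosomal proteins and hox genes. Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 in Python 3.11.15.

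Genes named in the text followed a rule fixed before the data were examined. It takes supt16h, then the 8 windows with the largest differences in each direction among called windows with all replicates of one group on one side of all of the other, 1 window per gene and without unnamed clone identifiers, then 3 members of each list with the lowest p, and always phc1, runx1, gata2b, notch1a and notch3. Of what these rules cover, 1 gene and 1 list are not reported here, and counts of named windows and of called lists leave them out. Other list members named beside their counts, and any gene named as such in the closing part, were chosen after their values were seen.

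Mutants and siblings share replicate numbers. Deviations from the group means correlated across windows between mutant and sibling of the same number (0.461, 0.513 and 0.534 for replicates 1, 2 and 3) and not between different numbers (-0.327 to -0.173, negative in part because deviations sum to 0 within a group), so the numbers were taken to pair the samples, from the data and not from a label. A fit with the replicate number as a block is given beside the number of calls, and for windows named by the rule and lists where it changes their call. It is also given for some windows whose call was lost with a replicate left out. Counts of list members with the block are given for part of the lists.

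The fit was tested on simulated data, with Gaussian noise around the real means and SDs of the 15431 windows and 50 windows changed by each of 4 sizes. For mutant against wildtype, 3 against 3, it recovered 6% of windows changed by 0.25, 70% of those changed by 0.5, 96% of those changed by 0.75 and 98% of those changed by 1 on the log2 scale, and called 5 unchanged windows among 140 calls. The real data gave 1790 calls, and with more calls the same adjusted threshold admits larger unadjusted p. The recovered shares therefore do not give the sensitivity of the real fit. Of 200 unchanged lists, 8 had a camera p under 0.05. The noise was drawn independently for each window and replicate, so the simulated genes of a list did not move together. It also held no library slopes and no correlation between samples of the same replicate number. The share of unchanged windows among the calls therefore does not carry over to the real data either. In the lists reported, the estimated correlation reached 0.477 (skeletal muscle). The simulation therefore does not show how often camera at the preset correlation calls such lists by chance.

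Alternatives covered the 6 against 6 fit, the replicate block, each replicate left out, other filters and thresholds, and, added after the data were seen, quantile and cyclic loess normalization, equal library medians, the library slope as a covariate or removed through technical repeats, a random block for biological replicates, each technical repeat alone and windows without overlap. Comparisons of promoters with distal peaks were not made, since every window analysed is centred on a start site. GC content was not examined, since no genome sequence was used here.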

Results

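Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in whole deyolked zebrafish embryos at 32 hours post fertilization. Embryos homozygous for a mutation in supt16h were compared with wildtype siblings. Supt16h is the large subunit of FACT, a histone chaperone that takes apart and reassembles nucleosomes ahead of and behind polymerases. Each group held 3 biological replicates in 2 technical replicates each, 12 libraries in all, made from 50000 cells per library. The table analysed held normalized log2 signal in windows of 4000 bp centred on annotated transcription start sites (GRCz10), so each value below describes a promoter and its surroundings, and distal elements were not analysed here. The read depth behind these values is unknown, since the table gives no counts. The median log2 signal of the libraries lay between 7.35 and 7.43. Values are given as mean ± SD over 3 biological replicates, and differences as mutant minus wildtype with the standard error (SE) from limma.

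The mutated gene itself was examined before all others. The window at the supt16h start site (chromosome 7, 1441156 to 1445156) had a log2 signal of 8.62 ± 0.12 (SD, n = 3) in the mutants and 8.55 ± 0.28 (SD, n = 3) in the siblings, a difference of 0.07 ± 0.13 (SE) with a 95% interval of -0.20 to 0.35 and a limma adjusted p of 0.776. Without wildtype replicate 2 the difference was -0.09 (adjusted p = 0.659). Accessibility of the promoter does not report a mutation within the gene, so this window checks no genotype. It also does not settle the sign of the comparison. The heading of the authors' deposited table reads mutant versus wildtype, yet its log2 fold change ran opposite to mutant minus wildtype in the library columns at all 2977 windows that the table calls. Directions below follow the names of the library columns, and every one of them would turn if those names were exchanged.

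The central question was which promoters differ in accessibility without Supt16h. Among the 8 most strongly raised promoters in the mutants were those of fzd8a, of sox19a and of the mitosis genes bub3 and plk1, and among the 8 most strongly lowered were the microRNA genes mir9-5 and mir9-2. fzd8a, which encodes a Wnt receptor, rose 2.10-fold (chromosome 24, 4416451 to 4420451, 1.07 ± 0.09, adjusted p = 2.4e-06). bub3, of the spindle checkpoint, rose 2.08-fold, sox19a, a SoxB1 factor of the early neural plate, 2.06-fold, plk1, a mitotic kinase, 2.04-fold, and alyref, an mRNA export adapter, 2.01-fold, each with an adjusted p of 2.8e-06 or less.

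gadd45aa and phlda3 stood 2.08-fold and 2.01-fold higher with a wide spread between mutant replicates (SD 0.40 and 0.43), and adjusted p of 0.0224 and 0.0436. These 2 calls were lost without mutant replicate 2 (adjusted p = 0.11 and 0.181) and without wildtype replicate 1 (0.089 and 0.137), replicate 2 (0.057 and 0.137) or replicate 3 (0.0947 and 0.135). Those fits ignored the pairing by replicate number. With the replicate block gadd45aa and phlda3 were both called (limma adjusted p = 2.1e-05 and 4.4e-06). Among lowered promoters, mir9-5 (chromosome 5, 47516673 to 47520673) fell by 0.74 ± 0.08 on the log2 scale (SE, adjusted p = 1.5e-05) and mir9-2 (chromosome 10, 43705715 to 43709715) fell by 0.65 ± 0.09 (adjusted p = 0.00019). Both belong to a microRNA family of the developing brain. birc6-as2, tmem125b, sema4e, a semaphorin, cdh12a, a cadherin, and tfpi2, a protease inhibitor, fell by 0.68, 0.66, 0.62, 0.58 and 0.58. fbxl18 fell by 0.64 ± 0.14 (adjusted p = 0.0135), and its call was lost without mutant replicate 1 (adjusted p = 0.0652) or 2 (0.0603). As the rule for naming them required, all 3 mutant replicates lay on one side of all 3 siblings at these windows.

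**Figure D1:**
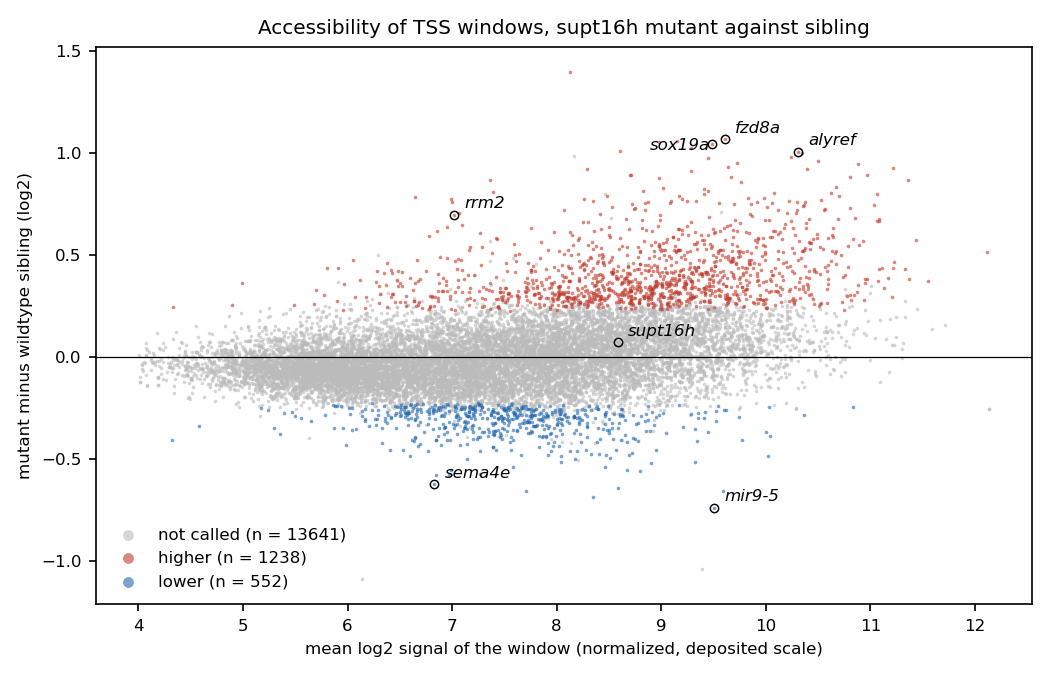
Difference in log2 signal, mutant minus wildtype sibling (y axis), against the mean log2 signal (x axis) for 15431 windows around transcription start sites; each point is a window, with 1238 called higher in red, 552 called lower in blue and circles at named genes. Higher calls grow more frequent with signal, while supt16h lies near 0.

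Across the promoters, 1790 of 15431 tested windows passed an adjusted p of 0.05 in limma, 1238 higher and 552 lower in the mutants, so 69.2% of the calls were higher. The median called change was 1.29-fold upward and 1.23-fold downward. All mutant replicates lay on one side of all siblings at 1773 of the called windows, and at 20.4% of the windows that were not called, where chance gives 10%. The share of windows called higher grew with signal, from 0.394% of those with a mean log2 signal between 4 and 6 to 42.2% of those at 10 or more. The latter held 186 higher and 6 lower windows, and 92 and 78 after cyclic loess normalization. The values of mutant libraries were on average more spread out, with a slope on the mean of all replicates of 1.02 ± 0.03 (SD, n = 3) against 0.98 ± 0.02 in siblings (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). Single libraries overlapped, at 0.991 to 1.08 in mutants and 0.905 to 1.04 in siblings. The technical repeats of wildtype replicates 1, 2 and 3 differed by 0.0928, 0.0965 and 0.0899, more than the groups did (0.0486). Those of mutant replicate 2 differed by 0.083, also more, but those of mutant replicates 1 and 3 by only 0.0068 and 0.00089. The share of higher calls was 55.8% after quantile normalization, 58.9% after cyclic loess normalization and 53.9% with that and the replicate block. It was 54.5% with the library slope removed through technical repeats, 76.9% of only 442 calls with the slope as a covariate and 81.0% with library medians set equal. All of these settings were chosen after the data were seen.

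The number of calls was 3621 with the replicate number as a block and 2969 with the 12 libraries kept apart, 6 against 6. It was 1116 without mutant replicate 3, and 1056, 1181 and 1134 without wildtype replicates 1, 2 and 3. It was 442 with the library slope as a covariate, a term that itself differs between the groups. Of the 47 called windows named in this section by the rule, 24 were then no longer called, and 1 of these, that of phc1, also changed sign.

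Genes that drive proliferation rose together. Of 31 measured genes of the cell cycle and DNA replication, 21 rose, none fell and 10 did not pass, and the median difference was 0.38 (1.30-fold) against 0.08 in random lists of equal signal. Adjusted over the list alone, 23 were higher. plk1 rose by 1.03 ± 0.08 (SE), aurkb, another mitotic kinase, by 0.77 ± 0.07, rrm2, a subunit of ribonucleotide reductase, by 0.70 ± 0.07, and ccna2 and pcna by 0.76 and 0.68. The inhibitors cdkn1bb and cdkn1ca, which restrain the cycle, were among the genes that rose (0.52 and 0.60), and mcm2, mcm4 and ccne2 lay at 0.01, -0.07 and -0.02 without passing. The list was higher by camera (adjusted p = 2.7e-18), and this was the only list whose call held with an estimated correlation (adjusted p = 0.0176). With the 12 libraries kept apart that call was lost as well (adjusted p = 0.0848 with an estimated correlation). After cyclic loess normalization 17 genes were higher, and 12 with the library slope as a covariate.

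Promoters of ribosomal protein genes rose in a similar share. Of 79 measured genes, 53 rose, none fell and 26 did not pass, with a median difference of 0.37 (1.29-fold) against 0.06 in random lists of equal signal. Adjusted over the list alone, 69 were higher and 1, rps8b, was lower (-0.20). rpl26 rose by 0.88 ± 0.08 (SE, adjusted p = 1.8e-06), rpl17 by 0.73 ± 0.08 and rpl24 by 0.64 ± 0.07. Camera called the list higher (adjusted p = 3.1e-35), a call lost with an estimated correlation (adjusted p = 0.0936 with an estimated correlation). After cyclic loess normalization 46 genes were higher, and 18 with the library slope as a covariate.

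**Figure D2:**
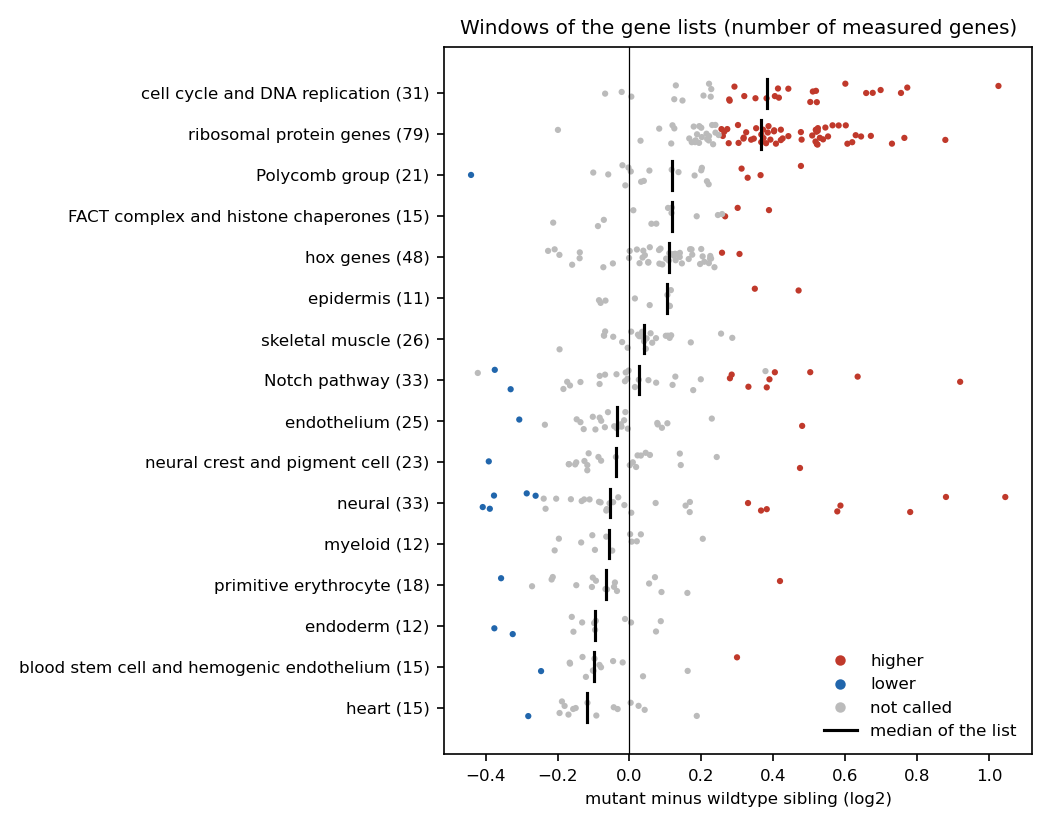
Difference in log2 signal, mutant minus wildtype sibling (x axis), for each measured gene of 16 lists (y axis, number of genes in parentheses); points are genes, red or blue where the window was called higher or lower, and black bars are list medians, with vertical scatter only for display. The medians of the cell cycle and ribosomal protein lists lie at 0.38 and 0.37, and those of the other lists between -0.12 and 0.12. The median of the Notch list is 0.03 as plotted and -0.07 after cyclic loess normalization.

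Neural genes moved in both directions. Of 33 measured genes, 8 rose, 5 fell and 20 did not pass (8 higher and 7 lower adjusted over the list alone). There were 6 higher and 3 lower after cyclic loess normalization, 6 and 0 with the library slope as a covariate, and 9 and 8 with the replicate block. Those that rose were the SoxB1 factors sox19a, sox3 and sox2 (1.04 ± 0.08, 0.88 ± 0.08 and 0.78 ± 0.08, SE), zic1 and zic2a (0.59 and 0.38) and the proneural or patterning genes ascl1b, neurog1 and nkx2.2a (0.58, 0.37 and 0.33). Those that fell were neurod1 and elavl4, of differentiating neurons (-0.41 and -0.38), isl2a, of motor and sensory neurons (-0.26), and gfap and fabp7a, of radial glia (-0.39 and -0.29). The median of the list was -0.06, against 0.04 in random lists of equal signal, and lay above those of 0.29% of them. Its mean was 0.07 and camera pointed upward without a call (adjusted p = 0.56), so the 3 measures differ in sign. Camera pointed downward after cyclic loess normalization (adjusted p = 0.843) and without mutant replicate 1 (0.898).

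In the Notch pathway, 9 of 33 measured genes rose, 2 fell and 22 did not pass (10 higher and 2 lower adjusted over the list alone). lfng, a glycosyltransferase that modifies Notch receptors, rose by 0.92 ± 0.08 (SE, adjusted p = 1.4e-06), the feedback inhibitor nrarpa by 0.63 ± 0.08 and the receptor gene notch3 by 0.50 ± 0.08 (adjusted p = 0.00058). hey2 and heyl, transcription factors induced by Notch, fell by 0.37 and 0.33. notch1a did not pass, at -0.00 ± 0.08 (95% interval -0.17 to 0.16). It was called lower with cyclic loess normalization and the replicate block together (-0.22, adjusted p = 0.0055). The list median was 0.03, against 0.07 in random lists of equal signal, and turned to -0.07 after cyclic loess normalization, with 5 genes higher and 7 lower. There were 12 and 4 with the replicate block, and 4 and 0 with the library slope as a covariate. Camera gave an adjusted p of 0.0565, and 0.0316 without wildtype replicate 2, while fry, which asks whether the genes move 1 way on balance, called the list (adjusted p = 0.0174). Camera with an estimated correlation did not call it (adjusted p = 0.444).

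Chromatin regulators were examined in the lists of chaperones and Polycomb genes. Of 15 measured genes of FACT and other histone chaperones, 3 rose, none fell and 12 did not pass (5 higher and 1 lower adjusted over the list alone, and 6 and 1 with the replicate block). The median was 0.12, against 0.03 in random lists of equal signal. The genes that rose were nasp, a chaperone of H3 and H1 (0.39 ± 0.08, SE, adjusted p = 0.0027), npm1a, nucleophosmin (0.30 ± 0.09, 0.0328), and supt4h1, an elongation factor subunit (0.27 ± 0.08, 0.0469). ssrp1a, the FACT partner of Supt16h, differed by 0.25 and did not pass. Camera gave the list an adjusted p of 0.0565, and 0.0339 with the replicate block. The list was also called without mutant replicate 1 (adjusted p = 0.0247) and without wildtype replicate 2 (0.0386) or 3 (0.0324). In the main fit, camera with an estimated correlation did not call it (adjusted p = 0.444). With the replicate block npm1a and supt4h1 were called too (limma adjusted p = 0.0012 and 0.0051). Leaving out a replicate kept their differences at 0.23 to 0.37 and 0.20 to 0.32, but their calls were lost in several of these fits. That of npm1a was lost without mutant replicate 3 or wildtype replicates 1 or 2 (adjusted p = 0.163, 0.156 and 0.107), and after cyclic loess normalization (0.36). That of supt4h1 was lost without mutant replicates 1 or 3 (0.145 and 0.0865) or wildtype replicates 1, 2 or 3 (0.0562, 0.0986 and 0.201).

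Of 21 measured Polycomb group genes, 4 rose, 1 fell and 16 did not pass, with the same 4 and 1 adjusted over the list alone, and 8 and 1 with the replicate block. The median was 0.12, against 0.08 in random lists of equal signal. jarid2b and suz12a, of the repressive complex that methylates H3K27, rose by 0.48 ± 0.08 and 0.33 ± 0.08 (SE, adjusted p = 0.00094 and 0.0095), eed by 0.36, and phc2b fell by 0.44 ± 0.08 (0.0012). phc1 (chromosome 16, 31986569 to 31990569) rose by 0.31 ± 0.10, with an adjusted p of 0.0427. That call was lost without mutant replicates 2 or 3 (adjusted p = 0.125 and 0.151), without wildtype replicates 1, 2 or 3 (0.215, 0.0503 and 0.0683), and with the library slope as a covariate (0.99, at -0.00). Camera called the list higher (adjusted p = 0.0321), a call lost with an estimated correlation (adjusted p = 0.579 with an estimated correlation). It was also lost without mutant replicates 2 or 3 (0.0962 and 0.0807), without wildtype replicate 1 (0.184), and after cyclic loess normalization (0.856, median -0.01).

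Of 48 hox genes, hoxb1b and hoxa1a, of the hindbrain, rose (0.31 ± 0.09 and 0.26 ± 0.08, SE) and 46 did not pass, and none passed adjusted over the list alone. With the replicate block 10 were higher and 2 lower. hoxa4a lay at 0.24 ± 0.08 (adjusted p = 0.0512, and 0.0102 with the replicate block). hoxb1b was not called without mutant replicate 3 (adjusted p = 0.143) or wildtype replicates 1 or 2 (0.0766 and 0.144). hoxa1a was not called without mutant replicates 2 or 3 (0.0511 and 0.176), without wildtype replicates 1, 2 or 3 (0.102, 0.125 and 0.105), or after cyclic loess normalization (0.0668). The median difference of 0.11 exceeded that of random lists of equal signal, at 0.00. Camera called the list (adjusted p = 0.0046), a call lost with an estimated correlation (adjusted p = 0.579 with an estimated correlation) and without mutant replicate 3 (0.0807).

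Blood stem cell genes were of interest because supt16h mutants are studied for blood formation. runx1, the transcription factor that blood stem cells need to arise, lay at 6.74 ± 0.09 in the mutants and 6.84 ± 0.06 in the siblings (SD, n = 3 each), a difference of -0.10 ± 0.08 (SE, 95% interval -0.26 to 0.06, adjusted p = 0.458). Its window lies on an unplaced contig. gata2b, of hemogenic endothelium, differed by -0.10 ± 0.08 (95% interval -0.27 to 0.07, adjusted p = 0.484). Of the 15 measured genes of this list, gfi1b rose (0.30 ± 0.07), gfi1ab fell (-0.25 ± 0.07) and 13 did not pass, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.212, median -0.10 against -0.03 in random lists of equal signal). That median lay above those of 3.06% of the random lists. The call of gfi1b was lost without wildtype replicates 2 or 3 (adjusted p = 0.0614 and 0.0555). That of gfi1ab was lost without mutant replicates 2 or 3 (0.055 and 0.141), without wildtype replicates 1, 2 or 3 (0.125, 0.0667 and 0.0986), and after cyclic loess normalization (0.0796).

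**Figure D3:**
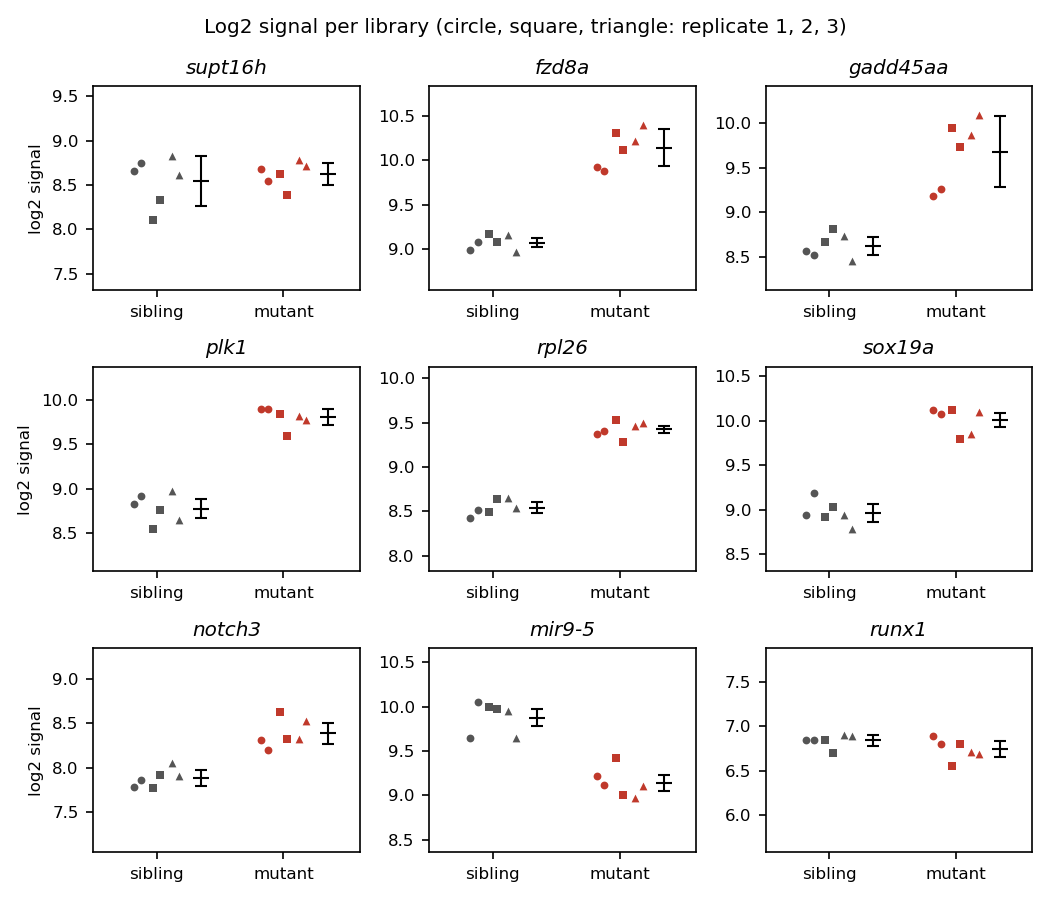
Log2 signal (y axis) of each library at 9 windows, siblings in grey and mutants in red; circles, squares and triangles mark replicates 1, 2 and 3 with their technical repeats, and the bars to the right give mean ± SD over 3 biological replicates. The y axes span equal ranges but start at different values. Mutants and siblings overlap at supt16h and runx1, and mutant replicate 1 lies below the other mutants at gadd45aa.

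For the tissue lists that follow, the signal is still that of whole embryos, so no difference is placed in a cell type. Of 25 measured genes of the vessel lining, 1 rose and 1 fell (the same adjusted over the list alone, and 2 and 2 with the replicate block). nr2f2, of veins, rose by 0.48 ± 0.09 and cdh5, of endothelial junctions, fell by 0.31 ± 0.08 (SE). The call of cdh5 was lost without wildtype replicate 3 (adjusted p = 0.0993) and after cyclic loess normalization (0.0535). fli1b lay at -0.24 ± 0.08 (adjusted p = 0.08, 0.0128 with the replicate block, and 0.0346 without mutant replicate 3). Among genes of primitive red cells, fech, of heme synthesis, rose by 0.42 ± 0.08 and nfe2 fell by 0.36 ± 0.08. In that list 16 of 18 genes did not pass (1 higher and 3 lower adjusted over the list alone, and 1 and 4 with the replicate block). cahz lay at -0.27 ± 0.09 (adjusted p = 0.0643, 0.012 with the replicate block, and 0.013 without mutant replicate 1). None of 12 myeloid genes passed, over all windows or adjusted over the list alone. Their lowest p belonged to coro1a, lcp1 and irf8, at -0.21, 0.20 and -0.20, each ± 0.07 or 0.08, which were called with the replicate block (adjusted p = 0.0153, 0.0117 and 0.0453). Camera called none of these lists (adjusted p = 0.441, 0.267 and 0.289), while fry called the myeloid list (adjusted p = 0.0444). Camera with an estimated correlation did not call the myeloid list either (adjusted p = 0.567). The medians of the endothelium, red cell and myeloid lists were -0.04, -0.06 and -0.06, against -0.04, -0.05 and -0.04 in random lists of equal signal.

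Markers of the remaining tissues bear on the makeup of the whole embryo. None of 26 skeletal muscle genes passed, over all windows or adjusted over the list alone. myod1 and mylpfa lay at 0.17 ± 0.08 and 0.25 ± 0.13 (SE), and mylpfa was called with the replicate block (adjusted p = 0.0387) and without mutant replicate 1 (0.047). Among heart genes, gata4 fell by 0.28 ± 0.08 and 14 of 15 did not pass. These included hand2 at -0.19 ± 0.07 and mef2cb, also a muscle gene, at -0.19 ± 0.07 (called with the replicate block, adjusted p = 0.039 and 0.0316). The call of gata4 was lost without mutant replicate 2 (0.116) or wildtype replicates 1 or 3 (0.0816 and 0.139). Among endoderm genes, nkx2.3 and ptf1a fell by 0.38 ± 0.07 and 0.32 ± 0.10 and 10 of 12 did not pass, with hnf4a at -0.13 ± 0.07. The call of ptf1a was lost without mutant replicates 2 or 3 (0.141 and 0.091), without wildtype replicates 1 or 3 (0.156 and 0.16), and after cyclic loess normalization (0.0916). Both lists had the same counts adjusted over the list alone.

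Among genes of neural crest and pigment cells, sox9a rose by 0.47 ± 0.09, tfap2e fell by 0.39 ± 0.07 and 21 of 23 did not pass. Of the latter, sox9b lay at 0.24 ± 0.10 (SE, adjusted p = 0.114, 0.0145 with the replicate block, and 0.045 without mutant replicate 1). Among epidermis genes, the keratins krt18 and krt8 rose by 0.47 ± 0.10 and 0.35 ± 0.10 and 9 of 11 did not pass. Of the latter, cdh1 lay at 0.11 ± 0.07 (adjusted p = 0.0449 with cyclic loess normalization and the replicate block together). The call of krt8 was lost without mutant replicates 2 or 3 (0.108 and 0.114) or wildtype replicates 1 or 3 (0.15 and 0.109). Counts adjusted over the list alone were the same for both. Camera called none of the muscle, heart, endoderm, neural crest and epidermis lists (adjusted p = 0.441, 0.0565, 0.0571, 0.441 and 0.228). The heart and endoderm lists were called lower without mutant replicate 1 (0.0247 each) and without wildtype replicate 2 (0.0276 and 0.0341). The epidermis and muscle lists were called higher with cyclic loess normalization and the replicate block together (0.0208 and 0.044) and with technical repeat 2 alone (0.00663 each). The heart and endoderm lists were called lower with technical repeat 1 alone (0.0342 each). The medians of the epidermis and muscle lists, 0.11 and 0.04, lay above those of 99.9% and 99.7% of random lists of equal signal, and that of the heart list, -0.12, above 1.39%. With a replicate left out, the epidermis median ran from -0.04 to 0.14, that of muscle from -0.05 to 0.10 and that of heart from -0.16 to -0.08. The endoderm and neural crest medians were -0.10 and -0.04, against -0.04 and -0.03 in random lists.

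Calls in the authors' deposited table were compared with those made here. At the promoters named above, the direction of difference was opposite in sign throughout: the table lists -1.44 for fzd8a and 0.97 for mir9-5. The authors' deposited table calls 2977 windows at an adjusted p of 0.05, and 1782 of them (59.9%, exact 95% interval 58.1% to 61.6%) were also called here, out of 1790. Of the 75 windows that also reach an absolute log2 fold change of 1 in the authors' deposited table, 72 were called here (96.0%, exact 95% interval 88.8% to 99.2%). Both intervals take windows as independent trials, though windows can overlap and all come from the same libraries, so they are too narrow. Across windows, which are not independent replicates, the fold changes of the authors' deposited table had a Pearson r of -0.986 with mutant minus wildtype and a slope of -1.52, so folds printed here are smaller than those in that table.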

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

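The windows tested in this part were chosen by rules fixed before the data were examined, while the test of library slopes was chosen only after these had been seen.

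Among 132 sets of 6 libraries, which were the named windows and the library slope in each group, 5 held a library set apart from the other 5 by more than the critical gap for 6 samples, where chance gives about 1 in 20 sets, or 6.6 here. The 6 libraries are 3 pairs of technical repeats and not 6 independent samples. At runx1, the second technical repeat of wildtype replicate 2 lay at 6.70, below the other siblings at 6.85 to 6.90. At jarid2b, the same library lay at 8.29, above the others at 7.94 to 8.06. At hnf4a, the second repeat of mutant replicate 2 lay at 5.47, above 5.10 to 5.20. At krt18, the second repeat of wildtype replicate 3 lay at 7.58, above 7.30 to 7.39, and at mef2cb the first repeat of that replicate lay at 6.80, above 6.68 to 6.72. No explanation was tested for these libraries.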

How the results depend on the processing

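Tests with quantile, cyclic loess or equal-median scaling, the library slope as a covariate or removed, a random block, technical repeats alone, a mean log2 value of at least 6 or windows without overlap were chosen only after the data were seen.

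From 1790 called windows (1238 higher, 552 lower), the replicate block gave 3621 (2160 and 1461), the 6 against 6 fit 2969 (1139 lower), cyclic loess normalization with the replicate block 3216 (1482 lower), the random block 857 lower, the library slope removed through technical repeats 939 lower, the library slope as a covariate 442 (340 and 102), technical repeat 2 alone 758 (524 and 234), an adjusted p of 0.01 880 (715 and 165), and an absolute difference of at least 1 gave 8 (8 and 0, where 3819 windows had an unadjusted p under 0.05). Leaving out a replicate gave 1056 to 2222 calls, 780 to 1587 higher and 248 to 635 lower. The other settings stayed within 1.5 times. Camera called 4 lists, 2 with the library slope, 7 with technical repeat 1 alone, 2 to 8 with a replicate left out, and 1 with an estimated correlation. The share of the authors' called windows also called here was 96.0% with an absolute log2 fold change of 1 as well. supt16h lay at -0.019 with technical repeat 2 alone and between -0.09 and 0.16 with a replicate left out.

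Direction turned for phc1 (-0.0039), runx1 (0.0051), sox9b (-0.018) and notch1a (0.10) with the library slope, and for notch1a with equal medians (0.028), technical repeat 1 (0.043) and a replicate left out (-0.054 to 0.052). Medians of lists whose direction by camera turned were, for endothelium, -0.015 (quantile), -0.0056 (loess), 0.025 (slope) and 0.017 (technical repeat 2). They were -0.072 (quantile), -0.064 (loess, with and without the block), -0.089 (technical repeat 2) and -0.062 to -0.038 (a replicate left out) for neural genes. They were -0.073 (quantile) and -0.065 (loess, with and without the block) for Notch, and with the slope -0.015 for Polycomb and 0.049 for primitive erythrocytes. For skeletal muscle they were -0.082 (slope), -0.014 (technical repeat 1) and -0.048 to 0.10 (a replicate left out).

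The cell cycle and ribosomal protein lists kept their camera call in each setting with the preset correlation. The replicate block turned no direction, gained 10 of the 65 named windows and the list of histone chaperones, and changed no other call among them. Lower counts at stricter thresholds follow from their construction, and otherwise the cause was not tested. Not run were the count models and count scalings planned for counts, pseudocounts, sums by title number, other promoter distances and the nearest window, which need counts, title numbers or distal windows not used here. Depth limits weak windows most, and it is unknown.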

Other observations

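The tests of symbol families, of neural lists, of the excess with library slopes removed and of windows near supt16h against runs of neighbouring windows were chosen only after the results they bear on were seen, and the last 2 replaced first versions of the same tests.

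Beyond the lists fixed in advance, genes were grouped by the letters that open their symbols, and 192 families with at least 10 genes were tested. Splicing factors of the srsf family had 11 of 16 promoters higher in the mutants (median 0.39, camera adjusted p = 3e-09), translation initiation factors of the eif family 16 of 59 (median 0.15, 2e-06), and proteasome subunits of the psmd family 6 of 16 (median 0.22, 0.00043). All 3 kept a camera call after cyclic loess normalization and lost it with an estimated correlation (adjusted p = 0.458 with an estimated correlation for each). Synaptotagmins, of synaptic vesicles, had 2 of 13 promoters lower (median -0.15, adjusted p = 0.0072), a call lost after cyclic loess normalization (0.0616) and with an estimated correlation (0.458). Olfactory receptors, 117 weak windows, had a median of -0.06 (0.0072), also lost after cyclic loess normalization (0.465) and with an estimated correlation (0.727).

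Neural genes were followed further because the SoxB1 factors had risen and neurod1, elavl4 and isl2a had fallen. The division was not clean, since gfap and fabp7a of radial glia had fallen and the proneural genes ascl1b and neurog1 had risen. Of the 33 genes 20 did not pass. These included the neuronal genes elavl3 and stmn1b at 0.16 and 0.07, and syt1a and snap25a at -0.23 and -0.11. In a list assembled here under the name of early progenitor genes, 10 of 25 were higher and 1 lower, led by sox11a (0.80 ± 0.08, SE), pou3f2b (0.77 ± 0.08) and pou3f3a (0.64 ± 0.07) (median 0.17, camera p = 0.00061, 0.0189 with an estimated correlation, and 0.0519 after cyclic loess normalization). The stage at which its members are active was not checked, so its rise does not tell progenitors from young neurons. In a list of glial genes, 2 of 12, plp1a and atp1a1b, were lower (median -0.18, camera p = 0.001, and 0.0966 with an estimated correlation). These genes were chosen after their values were seen.

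Fewer maturing neurons in the mutants is a hypothesis for the lowered neuronal promoters, and 23 maturing neuron genes outside the neural list had a median of -0.15, with nrxn1a, cplx2 and gad1b called lower. Limma's camera gave this list p = 0.000158 and, after cyclic loess normalization, 8e-05, a call lost with an estimated correlation (p = 0.0975). A delay shared by all tissues would lower other differentiated tissues as much. All 28 maturing neuron genes, those in the neural list included, had a median of -0.12. That of 104 genes of muscle, heart, pigment, blood and epidermis lay 0.121 higher (SE over genes 0.03). This SE takes genes as independent and leaves out the spread between replicates. The tissues also differed, with medians of -0.12 for heart, -0.06 for red cells and myeloid cells, and -0.04 for neural crest and pigment cells. Muscle and epidermis lay at 0.04 and 0.11, and endoderm, outside these 104 genes, at -0.10. The comparison therefore cannot decide on a general delay. Whether there are fewer neurons or less open promoters within them cannot be read from whole embryos and was not tested.

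The excess of higher over lower windows was weighed against chance and against the wider spread of values in mutant libraries. Of the 10 splits of the 6 replicates, 1, the real one, reached its 1790 calls, the highest of the others gave 2, and 10 splits are too few for a share under 0.05. Of the 4 splits that part all 3 replicate pairs, the real one called 3621 windows with the block and the other 3 called 0. Every other split mixes mutants with siblings, so a true group difference would widen its residual spread and lower its calls. The low counts of the other splits are therefore no measure of chance. With the slope of each library removed, at the sensitivity of each window measured between technical repeats, 1123 windows were higher and 939 lower. The main fit gave 1238 and 552, so lower calls rose more than higher calls fell. The excess went from 38.3% of calls to 8.92% (7.13% to 9.49% with a technical pair left out, and 17.9% after cyclic loess normalization). By these settings the spread of library values may account for most of the excess. With the library slope as a covariate 340 windows were higher and 102 lower (76.9% higher of 442 calls). That share cannot be set against the main fit, because fewer calls alone raise it. In the main fit itself it was 81.25% of the 880 calls at an adjusted p of 0.01. The covariate fit thus does not decide how much of the excess the spread accounts for, and this stays open. A first version of the test with slopes removed, which predicted 22.0% of the shift at called higher windows, was replaced because those windows had been chosen for being higher. Whether the slopes differ through the mutation or through the making of the libraries also stays open.

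Within 5 Mb of supt16h on chromosome 7, 14 of 59 windows were called (23.7%), against 8.63% expected from their signal, and 1 of 235 runs of as many neighbouring windows on other chromosomes had as large an excess. A first version that drew single windows at random was replaced, because it ignores that neighbours move together. A haplotype carried along with the mutant allele is a candidate explanation, since embryos sorted at supt16h would also differ at linked sites. At the starts of the 24 other chromosomes the largest excess was 7.77 percentage points, below that around supt16h, which argues against position near a chromosome end. An effect of the mutation on its neighbours stays open, as genotypes were not used here.

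lpcat4, 105 kb from supt16h and chosen after its values were seen, lay at 5.60 ± 0.11 in the mutants and 6.68 ± 0.48 in the siblings (SD, n = 3 each). The difference of -1.08 (95% interval -1.77 to -0.39) did not pass in limma without the replicate block (adjusted p = 0.074). The authors' deposited table gives an adjusted p of 1.9e-10. Of the 15 windows within 1.1 Mb of supt16h, 5 were called. These were nop10, emc4, drap1, zgc:63470 and rela, all higher (0.60, 0.31, 0.51, 0.44 and 0.32). tox4b, 49.2 kb from supt16h, lay at 0.14 and did not pass (limma adjusted p = 0.293). Strong windows were often called higher anywhere, as were 42.2% of those with a log2 signal of 10 or more, where drap1 lies.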
